A study of Mus musculus with 2 samples.

How the data were processed

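H3K27me3, the trimethylated form of histone H3 lysine 27 that Polycomb repressive complex 2 deposits, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse heart at embryonic day 14.5. Per the labels, the hearts came from pooled male and female embryos of a mixed B6NTac and B6NCrl background, and there were 2 biological replicates. The labels give a library size range of 300 to 500, without a unit. All samples belonged to 1 group, so the design held no second condition. A possible control experiment is named in the labels and was not used here.

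The deposited data were 4 peak lists in mm10 coordinates: a list for each replicate, a list called on the pooled replicates and a list of replicated calls. Per the file headers and notes deposited with them, each replicate list was made from that replicate's filtered alignments and a further file. The pooled list was made from both alignments, and the replicated list from the other lists. The rule by which a call entered the replicated list, the aligner and the peak caller are not given in the sources used here. A replicated peak is a member of that list, and was not in every case called in both replicates. Each line of the deposited lists gave a signal value, read here as the fold enrichment over background on a linear scale. Its formula is not given in the sources used here. The deposited lists also gave the −log10 of a p-value and the −log10 of a q-value for each peak. These values are the authors' own per peak, and were used to describe, rank or filter peaks within a list. Between replicates, the fold medians, the spacing of fold values and the folds at promoters of single genes were set side by side. The lowest −log10 p in the deposited lists lay between 2.01 and 2.05. The lists gave no read counts, so the sequencing depth of each replicate is unknown, and no interval that needs the depth is given.

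Chromosome lengths and promoter sequence came from GRCm38.p6, and gene models from GENCODE M21. The lists covered 20 chromosomes (1 to 19 and X), and 0 peaks reached beyond a chromosome end of this reference. The tables held 21755 protein-coding genes on these chromosomes. A promoter was the window of 1000 bp on either side of the annotated 5′ end of a gene. It was called covered when a replicated peak overlapped it by 1 bp or more, and the gene then took the fold of the strongest such peak. Promoter CpG content was the observed over expected ratio of CpG in the 500 bp on either side of the 5′ end, and genes were divided into 5 classes of equal size by it. Domains were replicated peaks joined when 3000 bp or less apart. Location was assigned per base in the order promoter, exon, intron and intergenic sequence.

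The share of covered promoters in each of 20 gene lists was compared with that of all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 20 lists. The lists held Hox cluster genes, neural regulators, skeletal muscle and limb regulators, endoderm and gut regulators, cardiac regulators, cardiac contractile and ion handling genes, endothelial, fibroblast and epicardial, blood and macrophage, and neural crest and glial genes. Further lists held germline genes, housekeeping genes, cell cycle inhibitors, secreted developmental signals, Polycomb subunits, and families taken by symbol: olfactory and vomeronasal receptors, Pax to Nkx transcription factors, Zfp-named zinc finger genes and ribosomal protein genes. The Polycomb list also held the H3K27 demethylase genes Kdm6a and Kdm6b. In the tests of gene lists the units were genes within a tissue. The p-values therefore compare genes and do not measure variation between hearts. Intervals on shares are exact Clopper-Pearson 95% intervals and cover counting error only. Neighbouring genes are not independent, so each test was repeated with list members at least 100000 bp apart. It was also repeated against 10000 random lists matched on CpG class.

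Overlap between replicates was compared with 100 random placements of peaks on their own chromosome outside assembly gaps. CpG classes were compared by a two-sided permutation test with 100000 resamples. The gene list test was tested on simulated lists over the same 21755 genes. Of 200 random lists of 22 genes, 4.0% were called, and of 200 lists of 22 genes drawn with an odds ratio of 6, 98.5% were called. For lists of 43 genes these shares were 2.0% and 100.0%. The overlap count recovered all 4000 planted overlaps. These were exact copies of replicate 1 peaks, so this result checks the counting alone. The test of fold by lineage within CpG classes, used in the closing part, was tried on 200 simulated data sets of 120 genes. It called 3.5% of those without a difference. The permutation test of fold without CpG classes was not simulated.

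Genes were named by a rule fixed, with the lists, tests and most alternatives, before the data were examined. It took the 10 covered genes of highest fold, with 1 gene per Hox cluster. It took the 3 members of highest fold in each list, and every covered member of the cardiac regulator and contractile lists. It added Nkx2-5, Gata4, Tbx5, Mef2c, Hand2, Myh6, Myh7, Tnnt2, Actc1 and Ttn whatever their state, and genes with a 5′ end in the 10 longest domains. It also took, per replicate, the 5 genes whose promoter lay under its strongest peaks without overlap in the other replicate anywhere along the peak. Other genes named singly were chosen after their values were seen.

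Alternatives covered windows of 500 and 2500 bp, any annotated transcript start in place of the 5′ end, the part of each list with the higher −log10 q, stricter overlaps, other joining distances (1000 and 10000 bp), pooled calls, and each replicate alone. An alternative added after seeing the data used the replicated calls that overlap both replicate lists. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.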

Results

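H3K27me3 was mapped by ChIP-seq in hearts of mouse embryos at day 14.5, a stage at which chambers and valves are formed and the heart beats. The 2 biological replicates came from pooled embryos of both sexes. The deposited lists held 88755 peaks for replicate 1, 45343 for replicate 2, 76319 for the pooled replicates and 36746 replicated peaks. Replicated peaks had a median width of 491 bp, a median fold enrichment of 3.55 and covered 31.7 Mb, or 1.24% of the sequenced genome. Read depth is unknown for both replicates. All coordinates are mm10.

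The question put to these lists was which genes carried the repressive mark in the developing heart. The tissue held several cell types, so a peak does not tell in which of them a gene was marked. Promoters of 3258 of 21755 protein-coding genes (14.98%) were covered by a replicated peak. In the separate lists the shares were 18.4% in replicate 1 and 14.6% in replicate 2. Among the genes with the highest fold were several known from the nervous system or other organs. Barhl1, a homeobox gene of the nervous system, had a peak of 13.3-fold enrichment at chromosome 2, 28910061 to 28918404, over its 5′ end. Hmx1, another homeobox gene, lay under a peak of 13.0-fold (chromosome 5, 35380031 to 35396465). Galnt9, a glycosyltransferase gene, followed with 12.7-fold (chromosome 5, 110542031 to 110546596), and Pcdh8, a protocadherin gene, with 12.1-fold (chromosome 14, 79767197 to 79771271). The zinc finger gene Egr4 reached 11.9-fold and the corepressor gene Skor2 11.8-fold. Hoxb8 and Lhx3, a LIM homeobox gene of pituitary and motor neurons, both reached 11.5-fold. Gabbr2, which encodes a GABA-B receptor subunit, and Neurog3, a regulator of pancreatic endocrine cells, reached 11.3-fold. All 10 of these promoters were also covered in each replicate list. The folds given are 1 value per peak, as called on the pooled replicates. In the separate lists the strongest peak at the Barhl1 promoter had 7.89-fold in replicate 1 and 7.62-fold in replicate 2. For Gabbr2 these values were 11.3-fold and 11.6-fold.

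Regulators of organs other than the heart were covered far more often than other genes. All 39 Hox cluster genes, which set position along the body axis, were covered (exact interval 91.0% to 100%; adjusted p = 2.85e-32, Fisher's exact test), with a median fold of 8.46. Hoxb8 and Hoxb9 lay under the same peak of 11.5-fold, and Hoxb2 under a peak of 10.7-fold. Such neighbours are not independent, and with members at least 100000 bp apart 6 of 6 Hox genes were covered (adjusted p = 2.37e-05, Fisher's exact test). Of 43 neural regulators, 42 were covered (97.7%, against 14.8% of all other genes; adjusted p = 4.55e-33, Fisher's exact test), with a median fold of 7.61 and with Lhx3, Neurog3 and Olig1 (11.02) highest. The neural gene not covered at its 5′ end was Otx1, which had calls in both replicate lists and a replicated peak at another annotated start. Skeletal muscle and limb regulators were covered in 19 of 22 cases (adjusted p = 5.72e-13, Fisher's exact test; median fold 8.76). Nkx3-2 (10.3-fold), Pitx1 (9.93-fold) and the signal gene Shh (9.80-fold) led that list, and the myogenic genes Myog, Myf5 and Myf6 were its members without a peak. Of the endoderm and gut regulators, 16 of 18 were covered (adjusted p = 1.75e-11, Fisher's exact test; median fold 7.02). Ptf1a, a pancreatic regulator, had 10.7-fold, Cdx2, an intestinal regulator, 10.3-fold, and Foxa1 8.43-fold, while Hnf4a and Hnf1a had no replicated peak.

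Genes of secreted developmental signals and of the large developmental transcription factor families were also covered more often than other genes. Of 56 genes for Wnt, Fgf, Bmp, hedgehog and related signals, 46 were covered (82.1%; adjusted p = 2.66e-28, Fisher's exact test), with Wnt7a at 10.4-fold and Wnt7b at 9.33-fold. The 10 members without a peak at the 5′ end were Fgf22, Fgf18, Fgf10, Wnt5a, Fgf1, Fgf7, Fgf6, Fgf23, Fgf20 and Bmp5. Of these, Fgf10 and Fgf20 had a replicated peak at another annotated start. In the Pax, Sox, Lhx, Tbx, Fox, Irx and Nkx families, taken with the sine oculis-like genes such as Six3, 87 of 119 genes were covered (73.1%; adjusted p = 4.57e-45, Fisher's exact test). Six3 itself (10.8-fold) and Nkx2-3 (10.5-fold) stood next to Lhx3 at the top, and 50 of the 119 genes also belonged to another list.

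Cardiac regulators were divided. Of 36 genes, 18 were covered (50%, exact interval 32.9% to 67.1%), against 14.9% of all other genes (adjusted p = 1.63e-06, Fisher's exact test). Tbx1, a gene of pharyngeal and outflow tract precursors, had the highest fold of the list (9.87; chromosome 16, 18587057 to 18592253). Shox2, which acts in the sinus node, had 7.21-fold, Six1 6.35-fold, Foxc1 5.84-fold, Isl1, a marker of cardiac precursors, 5.57-fold, and Pitx2, which sets left-sided identity, 5.45-fold. Foxh1 had 5.45-fold, Irx4 5.28-fold, Foxc2 5.26-fold, Tbx3 5.09-fold, Smarcd3 4.77-fold, Hand1 4.23-fold and Prdm16 and Irx3 4.00-fold. The pacemaker channel gene Hcn4 had 3.84-fold, Tbx2 3.81-fold and Irx5 3.80-fold. Nkx2-5, a core cardiac transcription factor gene, had a peak of 2.53-fold and 547 bp in its promoter window (chromosome 17, 26845622 to 26846168). This peak lay upstream of the 5′ end at 26845009 and had the lowest fold in the list. The Nkx2-5 promoter was called in replicate 1 and not in replicate 2. Irx3 was called in replicate 2 and not in replicate 1.

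The other 18 cardiac regulators had no replicated peak at the 5′ end, among them Gata4, Gata5, Gata6, Tbx20, Hand2, Mef2c, Hey1, Hey2, Srf and Myocd. For Gata4, Mef2c and Hand2 no annotated transcript start was covered and neither replicate list held a call. Myocd had a call of 3.02-fold in replicate 1, none in replicate 2, and a call of 3.09-fold in the pooled list. Tbx5, a regulator of the atria and left ventricle, had a call of 2.69-fold in replicate 2 and none in replicate 1, and another of its transcript starts was covered by a replicated peak. The share of covered cardiac regulators was below that of neural regulators (50% against 97.7%; p = 4.51e-07, two-sided Fisher's exact test).

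Genes of the contractile machinery and ion handling of cardiac muscle did not pass the test against other genes. Of 31 genes, 5 were covered (16.1%, exact interval 5.45% to 33.7%, against 14.97% of other genes; adjusted p = 0.802, Fisher's exact test). The share was 25.8% with windows of 2500 bp and with pooled calls, against 18.6% and 18.8% of other genes, and 29.0% against 17.7% with any annotated transcript start. None of these passed Fisher's exact test (adjusted p = 0.113 to 1 over all alternatives). The 5 genes covered at the 5′ end were Ckm, the muscle creatine kinase gene (5.33-fold), Obscn (5.07-fold), the sodium channel gene Scn5a (4.92-fold), Myl2, which encodes the ventricular myosin light chain (3.24-fold), and Nebl (3.14-fold). Myh6, Tnnt2, Actc1 and Ttn, which encode sarcomere proteins, had no call at the 5′ end in any of the 4 lists. Myh7 had none at its 5′ end either, although another annotated start of the gene was covered. Random lists matched on CpG class had mean shares of 13.5% for contractile genes and 18.1% for cardiac regulators. At the 5′ end, without such matching, the contractile share was below that of cardiac regulators (16.1% against 50%, p = 0.00462, two-sided Fisher's exact test). When any annotated transcript start counted, it was 29.0% against 52.8% and no longer passed the threshold (p = 0.0813, Fisher's exact test; 0.00108 to 0.0813 over all alternatives).

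**Figure D1:**
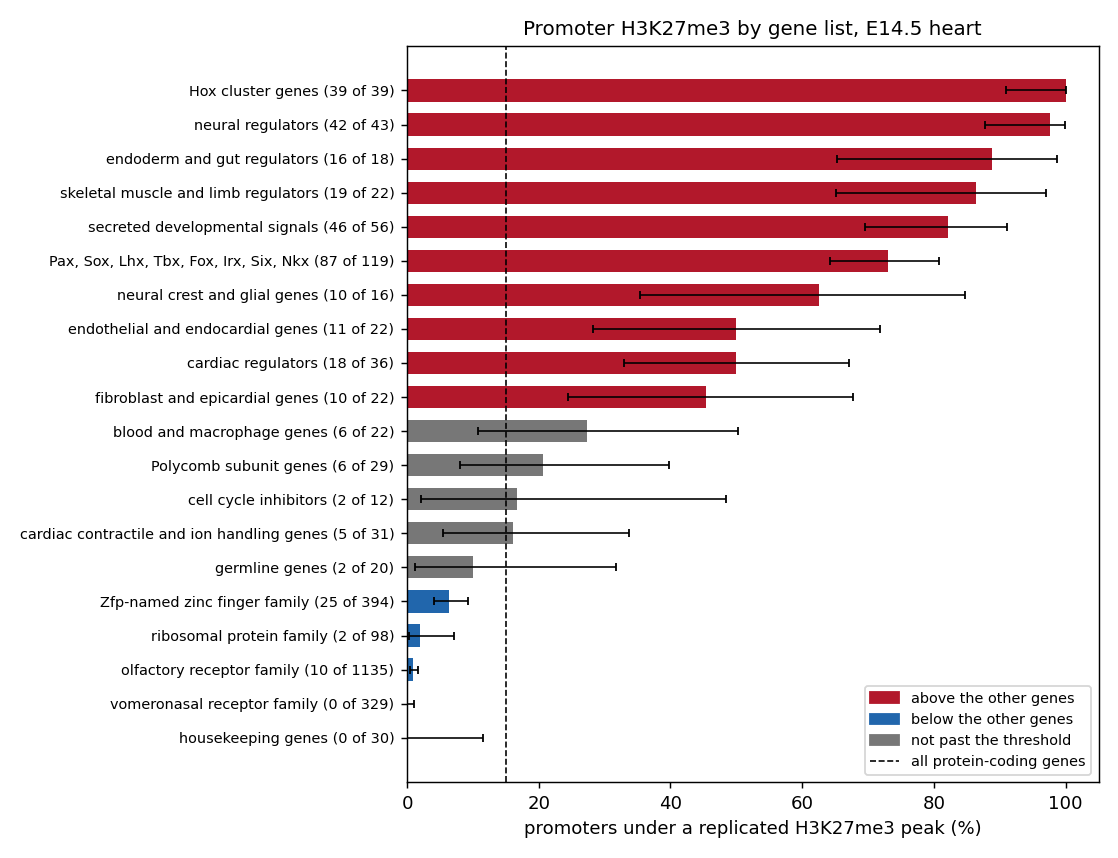
Percent of promoters under a replicated H3K27me3 peak (horizontal axis) in each of the 20 gene lists (vertical axis, with covered and total genes). Bars give the share, whiskers the exact 95% interval, the dashed line the 14.98% of all protein-coding genes, and colours the side on which the adjusted p passed 0.05; Hox and neural lists lie at 100% and 97.7%, cardiac regulators at 50% and contractile genes at 16.1%.

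The lists of genes of other cell types were covered at shares from 27.3% to 62.5%. Endothelial and endocardial genes were covered in 11 of 22 cases (50%; adjusted p = 0.000182, Fisher's exact test), with Sox18 at 9.06-fold, Erg at 6.65-fold and Sox7 at 6.45-fold. Fibroblast and epicardial genes were covered in 10 of 22 cases (45.5%; adjusted p = 0.000912, Fisher's exact test), led by Aldh1a2, an enzyme of retinoic acid synthesis (6.56-fold), Pdgfra (5.66-fold) and Col1a1 (5.15-fold). Neural crest and glial genes were covered in 10 of 16 cases (62.5%; adjusted p = 3.41e-05, Fisher's exact test), led by Foxd3 (9.96-fold) and the neuronal genes Elavl3 (8.43-fold) and Tubb3 (7.71-fold). Of 22 blood and macrophage genes, 6 were covered (27.3%; adjusted p = 0.159, Fisher's exact test), with Ikzf1 at 5.99-fold, C1qa at 5.15-fold and Tal1 at 5.10-fold. That list passed the threshold with pooled calls (45.5%; adjusted p = 0.00491, Fisher's exact test) and with replicate 1 alone, which covered 10 of its genes where replicate 2 covered 5. Over all alternatives its adjusted p ranged from 0.00440 to 0.873 (Fisher's exact test).

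**Figure D2:**
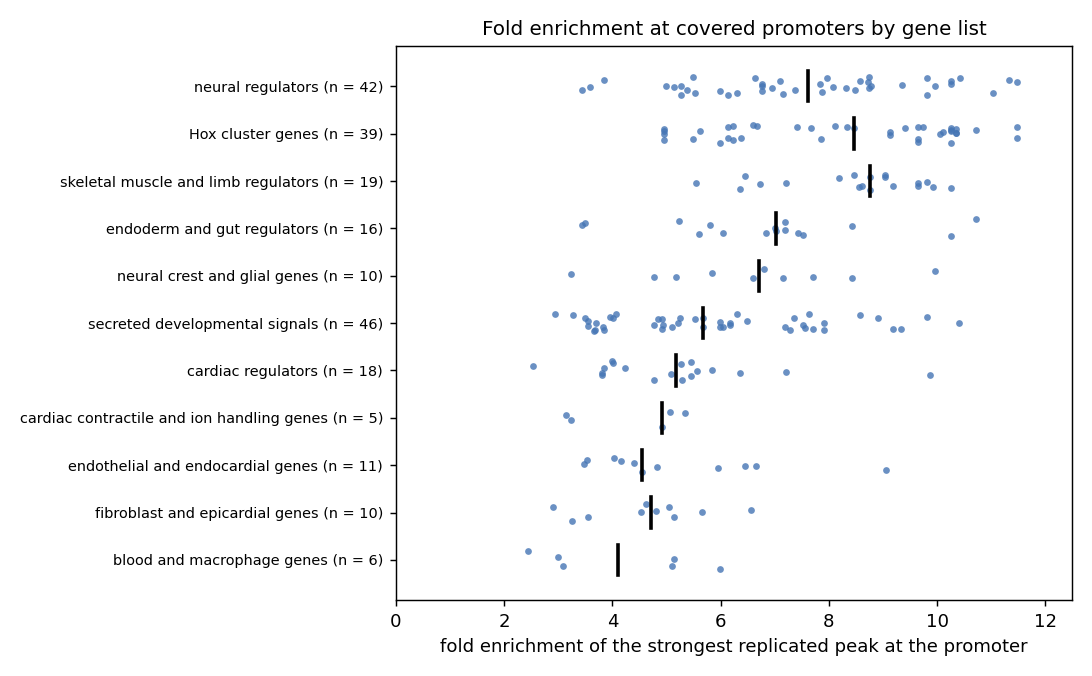
Fold enrichment, as deposited, of the strongest replicated peak at each covered promoter (horizontal axis) for 11 gene lists (vertical axis, n covered genes). Points are genes and black lines medians; the medians are 7.61 for neural regulators, 8.46 for Hox genes and 5.18 for cardiac regulators.

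Other lists lay near or below the remaining genes. Of 30 housekeeping genes 0 were covered, which allows a share of up to 11.6% by the exact interval, and 0 were called in either replicate (adjusted p = 0.0229, Fisher's exact test). This list missed the threshold with windows of 500 bp (adjusted p = 0.0583) and with the replicated calls of higher −log10 q (adjusted p = 0.0580), both by Fisher's exact test, and the lowest value over its alternatives was 0.00455. Olfactory receptor genes were covered in 10 of 1135 cases (0.881%; adjusted p = 1.07e-64, Fisher's exact test), with Olfr1377 (4.46-fold), Olfr95 (3.52-fold) and Olfr1410 (3.39-fold) highest. Replicate 1 alone covered 22 of these genes (1.94%) and replicate 2 alone 6 (0.529%), and the list stayed below the others with each. Random lists matched on CpG class had a mean share of 5.78%. With members at least 100000 bp apart, 5 of 279 olfactory receptor genes were covered (1.79%; adjusted p = 6.15e-14, Fisher's exact test). Of 329 vomeronasal receptor genes 0 were covered (adjusted p = 2.12e-23, Fisher's exact test), which allows up to 1.11% by the exact interval, and replicate 1 alone gave 1 gene. Zfp-named zinc finger genes were covered in 25 of 394 cases (6.35%; adjusted p = 3.31e-07, Fisher's exact test), and Zfp853 had 9.19-fold, Zfp575 8.18-fold and Zfp580 7.57-fold. The ribosomal protein family, taken by symbol, had 2 of 98 genes covered (2.04%; adjusted p = 7.40e-05, Fisher's exact test). These were Rpl3 (4.60-fold) and Rps6kl1 (3.19-fold), and the latter encodes a kinase-like protein, not a ribosomal one. Without the 10 genes named as kinases, 1 of 88 was covered.

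Germline genes (2 of 20; adjusted p = 0.797), cell cycle inhibitors (2 of 12; adjusted p = 0.776) and Polycomb subunit genes (6 of 29; adjusted p = 0.506) did not pass Fisher's exact test. The germline genes covered were Dmrt1 (6.29-fold) and Smc1b (3.55-fold), and replicate 1 alone or the pooled calls gave 5 genes (25%), also without passing the test. The cell cycle inhibitors covered were the neighbours Cdkn2a (5.01-fold) and Cdkn2b (4.87-fold), known Polycomb targets. The covered genes of the Polycomb list were Cbx8 (5.90-fold), Pcgf1 (4.47-fold), Cbx2 (3.57-fold), Cbx4, Phf19 and Aebp2. The 29 genes also held Kdm6a and Kdm6b, which encode H3K27 demethylases and not Polycomb subunits, and neither was covered. The share of this list was 10.3% against 12.4% of other genes with windows of 500 bp. With windows of 2500 bp it was 31.0% against 18.5%, and neither passed the test. With members at least 100000 bp apart, or against lists matched on CpG class, each of the 20 lists stayed on its side of the threshold, although blood and macrophage genes came close against the matched lists (adjusted p = 0.0572, permutation test).

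Promoters of intermediate CpG content were covered most often. From the lowest to the highest of 5 equal classes of CpG observed over expected, the shares were 3.61%, 12.2%, 28.5%, 18.9% and 11.6%, with 4351 genes in each. The highest class exceeded the lowest by 8.02 percentage points and the middle class exceeded the highest by 16.9 points (p = 1e-05 for each in a two-sided permutation test, the smallest p it can give). Without replicate 2 the former difference was 5.01 points. The median ratio was 0.558 in the middle class and 0.885 in the highest.

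Covered bases were concentrated at promoters and exons. Promoters took 15.9% of the bases under replicated peaks and 3.87% of the genome, a 4.10-fold excess, and the highest of 100 random placements gave 4.33%. Exons took 9.99% against 3.93% of the genome. Introns held 40.8% against 41.0%, and intergenic sequence 33.3% against 51.2%. The promoter share was 12.7% in replicate 1 and 17.7% in replicate 2. Some of the strongest peaks lay away from annotated 5′ ends. The highest fold of all, 13.9, belonged to a peak of 7271 bp inside Rbfox3, the gene of the neuronal protein NeuN (chromosome 11, 118566930 to 118574200). It overlapped an annotated exon and lay 90101 bp from the nearest 5′ end of a protein-coding gene, that of Engase.

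Neighbouring peaks formed long domains, the longest of them over the Hox clusters. Joined within 3000 bp, the replicated peaks made 12484 domains with a median length of 1204 bp. Of these, 1124 (9.0%) were 10 kb or longer and held 51.4% of all covered bases. The longest, of 268 kb, spanned HoxC at chromosome 15, 102883369 to 103151642, with the 5′ ends of 9 Hox genes from Hoxc13 to Hoxc4. The HoxB domain had 156 kb (chromosome 11, 96230658 to 96386983), HoxA 137 kb (chromosome 6, 52141904 to 52278530) and HoxD, with Evx2, 126 kb (chromosome 2, 74642579 to 74768993). From the first to the last Hox gene, replicated peaks covered 97.1% of HoxA, 83.8% of HoxB, 98.8% of HoxC and 97.0% of HoxD. Replicate 1 covered 90.6%, 79.1%, 94.97% and 90.9% of these intervals and replicate 2 91.9%, 75.4%, 95.1% and 90.3%.

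**Figure D3:**
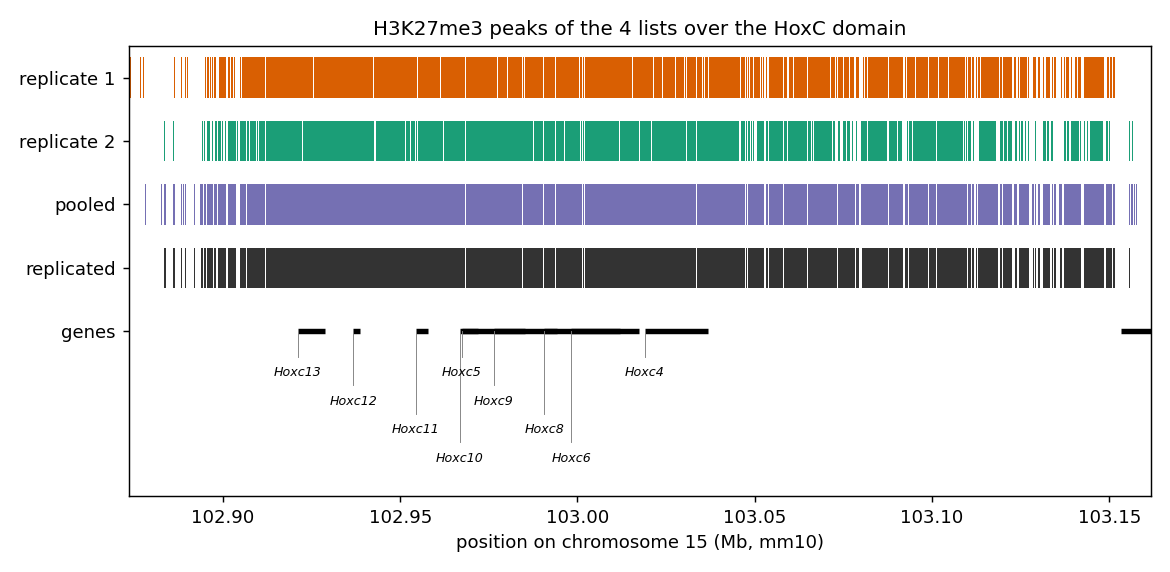
Peaks of the 4 deposited lists (upper rows, coloured blocks) and protein-coding genes (black bars, with names at the 5′ ends) over the HoxC domain; the horizontal axis is the position on chromosome 15 in Mb (mm10). Peaks of each list fill most of the interval from Hoxc13 to Hoxc4, of which 98.8% was covered by replicated peaks, and break up towards both ends.

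Beyond the Hox clusters, the domain of Sipa1l3 had 119 kb (chromosome 7, 29405546 to 29524449) and that of Pax7, a muscle and neural regulator, 110 kb (chromosome 4, 139750496 to 139860609). A domain of 107 kb on chromosome 9 (61261768 to 61368439) held the 5′ end of the non-coding gene B930092H01Rik and ended 3927 bp from the 5′ end of Tle3. On chromosome X a domain of 84.3 kb (103674525 to 103758798) overlapped the gene body of Slc16a2. It consisted of 64 peaks over 56.3% of its length, with a highest fold of 5.23, and replicates 1 and 2 covered 44.9% and 27.2% of it. Zic1 and Zic4, a neighbouring pair of neural regulator genes, shared a domain of 78.6 kb (chromosome 9, 91344626 to 91423183), and Tbx3 lay in a domain of 75.2 kb (chromosome 5, 119617919 to 119693068). Of the 10 longest domains, 6 to 8 were found again among the 10 longest with other joining distances or call sets.

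Chromosomes differed in the length covered. Chromosome X had 4.42 kb of replicated peaks per Mb, the lowest of the 20 chromosomes, against a median of 12.02 kb per Mb for the autosomes, which ranged from 6.75 on chromosome 3 to 21.8 on chromosome 11. The ratio of X to the autosomal median was 0.367, and it was 0.458 in replicate 1 and 0.326 in replicate 2. By number of peaks X was not the lowest chromosome, and the ratio was 0.607. No test was applied, since each chromosome gives a single value.

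Promoter calls were shared by both replicates for 2889 genes, which made up 91.2% of those covered in replicate 2 and 72.1% of those in replicate 1. Magee1 (5.77-fold), Etfa (5.59-fold), Cpn1 (5.49-fold), Dop1b (5.22-fold) and Gnat1 (5.14-fold) had the strongest promoter peaks of replicate 1 that overlapped no peak of replicate 2 along their whole length. Fmn1 (5.46-fold), Frzb, an inhibitor of Wnt signals (5.19-fold), Cux2 (5.05-fold), H2-Q7 (4.97-fold) and Intu (4.83-fold) had those of replicate 2 that overlapped no peak of replicate 1. Counted at the promoter window alone, 1120 promoters were covered in replicate 1 alone and 278 in replicate 2 alone.

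Over all peaks, the list of replicate 1 was 1.96 times as long as that of replicate 2 and covered 1.68 times as many bases. Of its peaks, 33.8% overlapped a peak of replicate 2 by 1 bp or more, and the highest of 100 random placements gave 2.009%. Of the replicate 2 peaks, 70.3% overlapped replicate 1 (highest random value 3.83%). When 50% of both peaks had to be shared, these overlaps were 15.3% for replicate 1 and 29.9% for replicate 2. With 5 equal classes by fold, overlap in the classes from lowest to highest fold was 15.5%, 17.1%, 23.9%, 36.4% and 76.1% for replicate 1. For replicate 2 it was 56.7%, 55.6%, 64.9%, 77.7% and 96.4%. The median fold was 3.30 in replicate 1 and 3.75 in replicate 2, with median widths of 272 bp and 293 bp. Fold values are specific to each list.

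**Figure D4:**
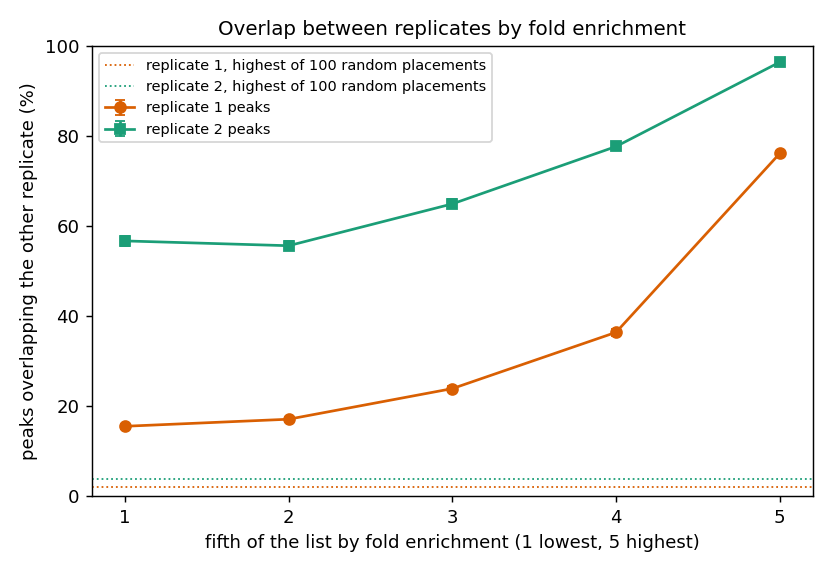
Percent of peaks of each replicate that overlap a peak of the other by 1 bp or more (vertical axis) in 5 equal classes of the list by fold enrichment (horizontal axis, 1 lowest and 5 highest). Whiskers are exact 95% intervals, smaller than the symbols, and dotted lines the highest of 100 random placements; in the highest class 76.1% of replicate 1 peaks and 96.4% of replicate 2 peaks overlapped.

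The replicated list was set against its sources. All 36746 replicated peaks had the coordinates and fold of a pooled peak. Of these, 22281 (60.6%) overlapped a peak of each replicate by 1 bp or more, 13090 overlapped a peak of 1 replicate alone and 1375 overlapped neither. The peaks that overlapped both held 82.7% of the covered bases, with a median fold of 3.94 and a median width of 696 bp. The remaining 14465 had a median fold of 3.19 and a median width of 334 bp. Nkx2-5, Aebp2 and Olfr1410 were among the named genes covered at the promoter in replicate 1 alone, and Irx3 and Cbx4 among those covered in replicate 2 alone.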

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

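The alternative that kept only replicated calls overlapping both replicate lists was chosen after seeing the data; the others were fixed before. Over all results, 225 of 253 alternatives stayed within a tolerance. For a tested result this was the same side of its threshold, for counts and lengths a factor of 1.5, for the ratio of list lengths a value above 1.5, for the promoter share and the X ratio 1 SD of the replicates, and for the overlap its 95% interval. The promoter share and X ratio of each replicate alone set that SD, so these 4 alternatives are not counted. For the gene lists this held for 194 of 200, and 18 of 20 lists held it under each of the 10 settings. Blood and macrophage genes passed the threshold at 40.9% with a window of 2500 bp (adjusted p = 0.0156), at 40.9% with any transcript start (adjusted p = 0.0114) and at 45.5% with pooled calls (adjusted p = 0.00491), by Fisher's exact test; with a replicate left out the share ranged from 22.7% to 45.5%, the higher value without replicate 2; the cause was not tested. Housekeeping genes kept a share of 0% with windows of 500 bp and with the calls of higher −log10 q, where fewer promoters were covered, and missed the threshold. The contractile list at 29.0% with any transcript start was no longer separated from cardiac regulators by Fisher's exact test (p = 0.0813); the cause was not tested. With the calls of higher −log10 q, which keeps 50 percent of each list by construction, the lists held 44377, 22671, 38159 and 18373 peaks (replicates 1 and 2, pooled, replicated), and joined within 3000 bp they held 30801, 13450, 22076 and 12484. Overlap between replicates left its interval under each alternative. For replicate 1 it was 24.3% with 50% of the peak covered, 15.3% with 50% of both peaks, 36.9% with the higher −log10 q and 50.1% with the same number of top peaks, and for replicate 2 58.5%, 29.9%, 74.8% and 57.6%. The promoter share of covered bases was 34.6% with promoters of 2500 bp, which are wider. Domains numbered 22076 from pooled calls and 8290 from calls that overlap both replicates. The ratio of X to the autosomes was 0.607 by number of peaks and 0.248 with the calls of higher −log10 q. No paired analysis was possible because all samples belong to 1 group. Depth is unknown, so a promoter without a call cannot be told to lack the mark.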

Other observations

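The families and genes in this paragraph were chosen after the strongest peaks had been seen. The adjusted p-values do not account for that choice. Among 10 families taken by symbol, 7 were covered more often than other genes and 1 less often after Benjamini-Hochberg adjustment of Fisher's exact test. Potassium channel genes were covered in 62 of 93 cases (66.7%; adjusted p = 1.58e-28, Fisher's exact test), led by Kcnk12, Kcnk9 and Kcnk15. Glutamate and GABA receptor genes were covered in 23 of 41 cases (56.1%; adjusted p = 6.45e-09, Fisher's exact test), with a median fold of 6.29. Collagen genes (44.4%), semaphorin genes (45.0%), protocadherin genes outside the clusters (50%), keratin genes (34.0%) and receptor genes named Gpr (31.5%) followed. Clustered protocadherin genes (12.3%; adjusted p = 0.711) and proteasome genes (7.50%; adjusted p = 0.294) did not pass Fisher's exact test. Mitochondrial complex I genes were covered in 1 of 46 cases (2.17%; adjusted p = 0.0138, Fisher's exact test), and the gene was Ndufa4l2.

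Non-coding genes were covered too, at lower shares than the 14.98% of protein-coding genes. The 5′ end of 444 of 5305 lincRNA genes (8.37%) and 143 of 2196 microRNA genes (6.51%) lay within 1000 bp of a replicated peak. The share was 13.3% for antisense genes, 1.67% for processed pseudogenes and 0.863% for snoRNA genes. No test was applied to these shares. Hotair (9.41-fold, chromosome 15, 102944062 to 102947730), Hottip (5.98-fold) and Hotairm1 (4.95-fold) lay inside the Hox domains, as did Mir196a-1 (11.5-fold) and Mir10a (10.3-fold). Mir9-3hg, host of a microRNA of neural cells, had 8.91-fold in a domain of 73.4 kb (chromosome 7, 79492708 to 79566111). The cardiac microRNA genes Mir1a-1, Mir208a and Mir133a-1 had no replicated peak, nor had the imprinted genes H19 and Meg3 or the X inactivation gene Xist, whereas Tsix, antisense to Xist, had 3.09-fold. The peak of highest −log10 p in replicate 1 lay over the imprinted gene Dio3 (11.6-fold, chromosome 12, 110275279 to 110283452). In replicate 2 it was a peak annotated as ribosomal RNA (chromosome 17, 39843075 to 39846774), with a −log10 p of 45.4 and a fold of only 2.71, which ranked 42968 of 45343 by fold.

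Of the tests in the next 3 paragraphs, those of weak calls, of sequencing depth, of gene density on X and of repeats were chosen after the results were seen, and those of CpG content and annotated starts before. No biological explanation was tested for any of them, since all samples belong to 1 group.

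The list of replicate 1 was 1.96 times as long as that of replicate 2. The additional peaks were mostly weak, which is in line with calls near the threshold: 88.2% of the 58743 peaks found in replicate 1 alone had a fold below the median of its shared peaks, and their median width was 240 bp against 458 bp. The same held for 81.9% of the peaks found in replicate 2 alone, so weak calls are the less shared ones in both lists and do not say why replicate 1 has more of them. Deeper sequencing of replicate 1 may be a cause. The step between its most common fold values was 1.12 times that of replicate 2 (0.275 against 0.244), where a larger background count would give a smaller step under common formulas, but the caller is not given in the sources used here, so depth and enrichment cannot be told apart.

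At covered promoters, genes of the cardiac, endothelial and fibroblast lists had lower fold than regulators of other lineages. The mean log2 fold was 2.22 ± 0.40 (SD, 42 genes of these lists, the contractile list included) against 2.88 ± 0.42 (SD, 75 genes of the neural, muscle and endoderm lists), leaving out Shox2 and Six1, which are in both, and the difference was -0.66 (p = 1e-05, permutation test, the smallest p it can give). The 18 covered cardiac regulators, with Shox2 and Six1, had a mean of 2.30. The neural, muscle and endoderm lists had means of 2.86, 3.06 and 2.71. The 42 genes also held contractile genes and cell type markers, so gene class differed between the sides, and its effect was not tested. The 10 covered neural crest and glial genes, not among the 42, lay nearer the other lineages (mean 2.65). In a comparison chosen after the results were seen, these and the blood and macrophage genes were added and Phox2b, which is on both sides, was left out. The difference was then -0.62 (p = 1e-05, permutation test). The tests argued against promoter CpG content as the whole cause, since the difference within CpG classes was -0.65. They argued likewise against an annotated 5′ end away from the peak, since the strongest peak within 2500 bp of any transcript start gave -0.68 (each p = 1e-05, permutation test). Each fold belonged to a whole pooled peak, which can extend beyond the promoter window. The comparison was not repeated with the folds of each replicate list, and the effect of peak width was not tested. Other explanations were not tested either.

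Chromosome X had the lowest covered length per Mb, with a ratio of 0.367 to the autosomal median. Fewer genes per Mb cannot be the whole cause, since 7.49% of 948 X promoters were covered against 16.4% of random autosomal lists matched on CpG class (p = 2e-04, permutation test over 10000 lists, the smallest p they can give). Repeats masked in the reference, which make up 46.8% of X and a median of 33.4% of the autosomes, account for a part at most. When only covered bases outside repeats were counted, per Mb outside repeats, the ratio was 0.451 (0.557 in replicate 1 and 0.396 in replicate 2). X was then the lowest of the 20 chromosomes. Multi-copy sequence outside the masked repeats was not examined. The number of X copies in pooled male and female embryos, and broad weak enrichment that a peak list may miss, were not tested and stay open.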
